A study of Caenorhabditis elegans with 4 samples.

How the data were processed

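LAG-1 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans grown to the L4 larval stage. The series holds 4 samples: 3 LAG-1 ChIP replicates, which the series describes as independent biological replicates, and 1 input DNA sample. The labels give germline as the cell type, while the protocol in the labels describes lysates prepared from animals. The labels give the same strain name, Bristol, for the ChIP samples and the input. Groups and replicate numbers were taken from the sample titles. The file headers name the ChIP libraries by another name than LAG-1, one that contains the word Biotag and whose meaning is not given in the sources used here, so that the libraries are LAG-1 ChIP rests on the labels. The input sample entered only as the control of each deposited peak list, and no signal track or read count was used here.

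Each ChIP replicate has 1 peak list. Per the file headers, the authors called peaks separately for each replicate with MACS version 2.1.1.20160309 against the same input library. The headers give single-end tags of 50 bp, an effective genome size of 90000000 bp and summit calling within peaks. The submitters' processing notes give ce10 as the genome build. The aligner is not given in the sources used here. Per the file headers, at most 1 tag per position was kept, and the larger of the ChIP and input libraries was sampled down to the smaller. The redundant share removed was large. Of 5074266 tags in replicate 1, 784774 (15.5%) were kept. The corresponding numbers were 509715 of 5441972 (9.37%) in replicate 2 and 1305672 of 3475891 (37.6%) in replicate 3. In the input, 15313802 of 17914470 tags (85.5%) were kept. Each list was therefore called on a sampled part of the input of the same size as the ChIP library. The fragment length that MACS used also differed, at 77, 125 and 55 bp in replicates 1, 2 and 3, and it equalled the narrowest peak in each list.

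The deposited pileup is a signal, the number of extended tags stacked at the summit, and it was not scaled between libraries. The deposited fold enrichment is the ratio of the pileup to the local input background, as the authors' peak caller gave it. The deposited significance columns are −log10 p-values and −log10 q-values per summit. The series states thresholds of fold above 2.0 and false discovery rate below 0.05. Every deposited summit met both, so the lists were used whole. Fold and pileup per peak are the authors' values throughout. A peak here is 1 interval, and where it held several summits the summit of highest fold stood for it.

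The local input background was recovered from fold and pileup, since MACS adds a pseudocount of 1 to both terms of its ratio. The recovered values were checked by rebuilding the deposited p-values with a Poisson distribution. The rebuilt −log10 p lay within 0.05 of the deposited value for 100% of the summits in replicates 1 and 3 and for 99.9% in replicate 2. The lowest possible background, sampled tags times fragment length over genome size, was 0.671, 0.708 and 0.798 tags. It is called the genome-wide level below, and local background is given as a multiple of it.

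Peaks of the 3 lists were merged where they overlapped by at least 1 bp. A merged region was called shared when each of the 3 lists had a peak in it. The number of shared regions was tested against 1000 random placements of each list's peaks within their own chromosomes, one-sided. The smallest p-value these placements can give is 0.001. Pairwise overlaps were tested the same way, with Benjamini-Hochberg adjustment over the 3 pairs. Chromosome lengths were not used here, and the end of the last peak on each chromosome over the 3 lists stood for its length. The share of regions on X was compared with that extent by 100000 random draws, two-sided, with Benjamini-Hochberg adjustment over 5 such tests. This test had been planned for known chromosome lengths, and the use of the extent in their place was chosen after the lists were seen. Regions are not replicates, so correlations of fold across regions carry no p-value. The count of shared regions and its placement test were tested on simulated lists with the real numbers and widths of peaks. With 299 planted shared places 299 were found, with 100 planted 100 were found, and with none planted 0 were found. The planted peaks had nearly the same centre in each list, so finding them was fixed in advance. Summits of the real shared regions spread over a median of 134 bp, a setting that was not simulated. The tests of runs, chromosome ends and X were not tested on simulated data.

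The examination of runs, blocks and chromosome ends was chosen after the lists were seen. A run is at least 3 shared regions with gaps of at most 10 kb. A block was drawn around each run by joining the peaks of all lists across gaps of at most 5 kb, so the 5 kb outside each edge hold no peak by construction. Each block was compared with flanks of its own length on either side. A region was at a chromosome end when it reached into the first or last 1 kb of the extent. Since the extent ends at the last peak, some list has a peak at each right end by construction. The right end of chromosome II was left out by hand, because chromosome II is known to continue well beyond its last peak.

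The text names the 20 shared regions chosen by a rule fixed before the data were examined. Each list was ranked by fold, each shared region took the largest of its 3 ranks, and the 20 regions with the lowest such rank were taken. Positions are 1-based and on ce10. The reference gene table at hand belongs to another assembly, WBcel235, and coordinates were not moved between builds. Assignment of regions to genes, the 20 gene and cell type marker lists, the position relative to exons and promoters and the search for the LAG-1 motif were therefore not analysed here.

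A single pileup carries counting error. The median peak had a pileup of 13 tags in replicate 1, with an exact Poisson 95% interval of 6.92 to 22.2. It was 12 tags in replicate 2 (6.20 to 21) and 22 tags in replicate 3 (13.8 to 33.3). These intervals cover counting error of the pileup only, and none was computed for the input background. Alternatives were a 50% reciprocal overlap, summits within 200 bp, fold of at least 3, false discovery rate below 0.001, lists of equal length, presence in at least 2 lists, leaving out each replicate, and pileup in place of fold. Added after the lists were seen were rotation of whole lists along the chromosomes, a limit on local background, removal of chromosome ends and wide regions, removal of 3 runs of low input background, counting neighbouring regions once, left ends alone, and values of r with no agreement between replicates. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.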

Results

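LAG-1 is the C. elegans member of the CSL family, the DNA-binding transcription factors through which Notch receptors act on their target genes. In the germline the receptor is GLP-1, and lst-1 and sygl-1, both on chromosome I, are known targets of this pathway that keep germ cells in the stem cell state. The series maps where LAG-1 sits on the genome in 3 ChIP-seq replicates, each compared with input DNA. The comparisons that this design allows are ChIP against input within each replicate and the replicates against each other. Regions are described by their ce10 positions, and which genes they lie at was not analysed here.

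LAG-1 ChIP gave 1221 peaks in replicate 1, 1148 in replicate 2 and 799 in replicate 3. The peaks covered 296469, 414498 and 185952 bp, which is 0.329%, 0.461% and 0.207% of the effective genome size. Most were narrow, with median widths of 132, 194 and 122 bp in replicates 1, 2 and 3. Peaks with more than 1 summit numbered 264, 233 and 245. The median fold over input was 4.70 in replicate 1, 4.71 in replicate 2 and 4.50 in replicate 3. The highest folds were 50.3, 69.0 and 40.5. Replicate 3 had the fewest peaks although it kept the most tags, 1305672 against 784774 and 509715 in replicates 1 and 2.

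Merging the lists gave 1776 regions, of which 319 had a peak in all 3 replicates and 601 in at least 2. Random placement of the same peaks gave at most 2 regions shared by all 3 lists in 1000 placements (one-sided permutation p = 0.001, the smallest these can give). The shared regions had a median width of 502 bp and ranged from 128 to 11163 bp. Their median folds were 6.0, 5.86 and 5.32 in replicates 1, 2 and 3. The number depends on the strictness of the match, and at 50% reciprocal overlap 145 regions were shared. It also depends on input background, and 60 were shared when only peaks below 2 times the genome-wide level were kept. Without replicate 3, 500 regions were common to the other two lists.

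**Figure D1:**
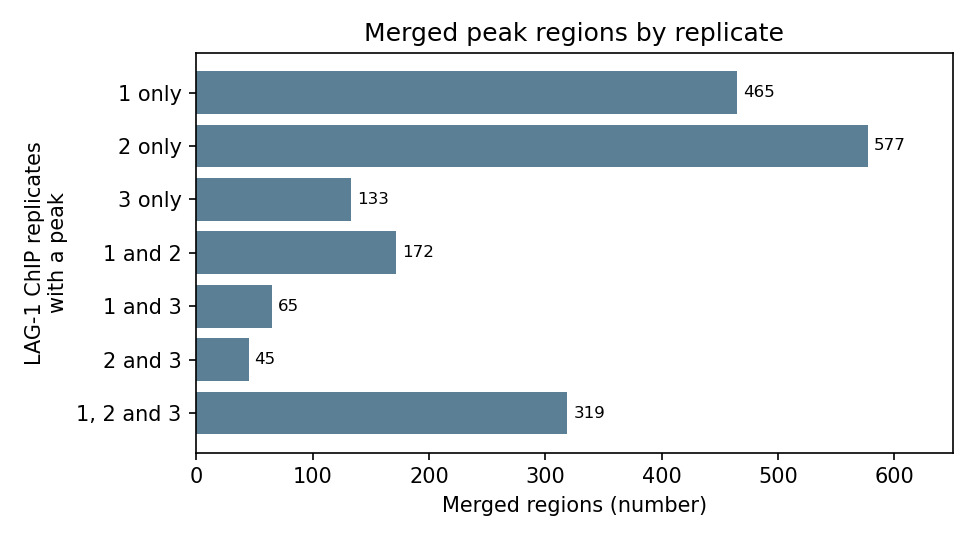
Number of merged regions (horizontal axis) for each combination of LAG-1 ChIP replicates with a peak in the region (vertical axis). Replicates 1 and 2 have 465 and 577 regions of their own, replicate 3 has 133, and 319 regions are in all 3 lists.

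At an overlap of 1 bp or more, replicate 3 overlapped the other lists most completely. Of its peaks, 72.2% overlapped a replicate 1 peak and 74.3% a replicate 2 peak. In the other direction, 40.0% of replicate 1 peaks and 34.0% of replicate 2 peaks overlapped a peak of replicate 3. Replicates 1 and 2 shared 55.9% and 45.5% of their peaks with each other. Random placement gave at most 1.88% in any of these comparisons (one-sided permutation, adjusted p = 0.001 for each of the 3 pairs). At 50% reciprocal overlap the order of the lists changed. Replicate 3 then shared 36.3% of its peaks with replicate 1 and 19.3% with replicate 2, against 24.4% and 26% between replicates 1 and 2. Peaks found in 1 list only were narrower and lower than those in shared regions. In replicate 1 their median width was 95 bp against 239 bp, and their median pileup was 8 against 26 tags. In replicate 2 these medians were 144 against 397 bp and 9 against 26 tags, and in replicate 3 they were 70 against 156.5 bp and 9 against 28 tags. Folds differed less, with medians of 4.50 against 5.29, 4.67 against 5.75 and 4.35 against 4.68. Of the peaks in the highest quartile of fold, 66.7%, 58.5% and 83.7% lay in shared regions in replicates 1, 2 and 3. Of those in the lowest quartile, 30.1%, 25.5% and 70.9% did.

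Across the 319 shared regions, log2 fold was correlated between replicates. Pearson's r was 0.71 for replicates 1 and 2, 0.71 for replicates 1 and 3 and 0.67 for replicates 2 and 3. Spearman's rho was 0.63, 0.65 and 0.62. These values are across regions, which are not independent replicates, and all folds share the same input. With pileups shuffled across regions over their real backgrounds, r averaged 0.35, 0.38 and 0.36 in 1000 shuffles and was at most 0.50, although 11.9% of such folds lay below 2, where the lists hold none. With folds shuffled within 10 strata of local background, r averaged 0.06, 0.04 and 0.05 and was at most 0.24. The 20 leading regions contributed to them, and without these r was 0.56, 0.56 and 0.51. For a single region, the difference in log2 fold between a pair of replicates had an SD of 0.62, 0.52 and 0.65 in the same order. Fold differences between regions smaller than this were within the spread between replicates.

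**Figure D2:**
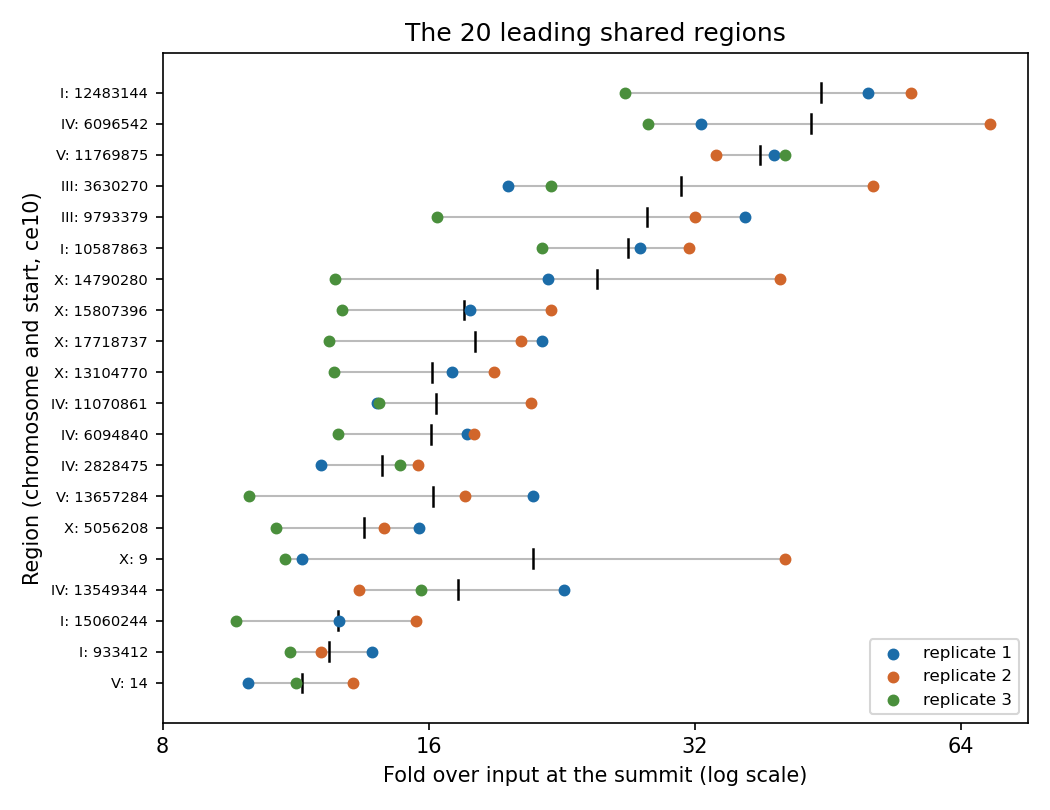
Fold over input at the highest summit (horizontal axis, log scale) in the 20 leading shared regions (vertical axis, chromosome and ce10 start). Dots are the 3 replicates, black ticks their mean and grey lines their range, and the region starting at 12483144 on chromosome I has folds of 50.3, 56.2 and 26.7.

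The region placed first by the largest of its 3 ranks lay on chromosome I from 12483144 to 12484314. It ranked 1, 2 and 3 by fold in replicates 1, 2 and 3. Its fold over input was 50.3 in replicate 1, 56.2 in replicate 2 and 26.7 in replicate 3, a mean of 44.4 ± 15.6 (SD, n = 3). The summit pileups there were 146, 224 and 105 tags, or 94.8%, 89.6% and 95.5% of the most that 1 tag per position allows. These folds can therefore be compressed, and their mean and SD need not measure enrichment. The summits of the region were at 12483808, 12483808 and 12483811, a spread of 3 bp. Another leading region on chromosome I ran from 10587863 to 10588876, with folds of 27.7, 31.5 and 21.5 and summits within 4 bp of each other. On chromosome V, the region from 11769875 to 11770872 had folds of 39.3, 33.8 and 40.5 and summits within 5 bp. On chromosome III, the region from 9793379 to 9794166 had folds of 36.5, 32 and 16.3, and the region from 3630270 to 3630840 had folds of 19.7, 50.9 and 22. Their summits agreed within 23 and 25 bp. Other regions agreed less closely. Over the 20 leading regions the spread of the 3 summits had a median of 48.5 bp, and in 4 it was at most 10 bp. Over all 319 shared regions the median spread was 134 bp, and 27.3% had a spread of at most 50 bp.

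Chromosome IV held the region with the highest fold of any list. It ran from 6096542 to 6100794, with folds of 32.5, 69.0 and 28.3 at summits spread over 496 bp. A second leading region, from 6094840 to 6096504, lay beside it with folds of 17.7, 18 and 12.6. Both belonged to a block of peaks from 6086914 to 6123959, 37.0 kb long, which held 21 shared regions. The block had 59, 36 and 55 peaks in replicates 1, 2 and 3, which covered 46.2%, 39.1% and 47.9% of it. The median fold of these peaks was 5.41, 6.06 and 5.97. The flanks of equal length, empty for their first 5 kb by construction, held 1 peak on the left and 0 on the right over the 3 lists. The other leading regions on chromosome IV started at 11070861, with folds of 14, 20.9 and 14.1, at 2828475, with 12.1, 15.6 and 14.8, and at 13549344, with 22.7, 13.3 and 15.7. The summits of the last agreed within 4 bp, while those of the regions starting at 11070861 and 2828475 spread over 1051 and 1565 bp.

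**Figure D3:**
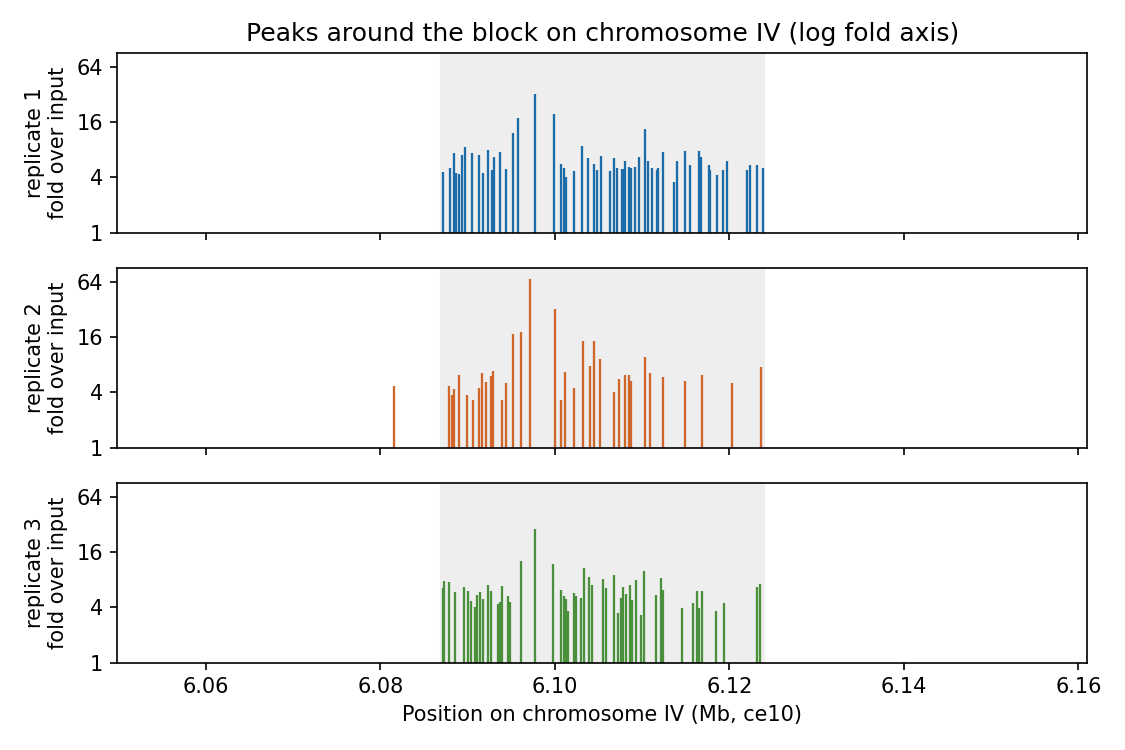
Peaks on chromosome IV (horizontal axis, ce10 position in Mb) as lines at their summits, with fold over input on a log vertical axis, for replicates 1, 2 and 3. The shaded block from 6086914 to 6123959 holds 150 peaks over the 3 lists, and the flanks shown hold 1.

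Chromosome X held 6 of the 20 leading regions. The region from 14790280 to 14790891 had folds of 21.9, 40.0 and 12.5, and the region from 13104770 to 13105195 had folds of 17, 18.9 and 12.5. The region from 15807396 to 15811206 was 3811 bp wide, with folds of 17.8, 22 and 12.7. The region from 5056208 to 5057277 had folds of 15.6, 14.2 and 10.7. The first and the last shared region of the chromosome were among the leading regions. The first, from 9 to 333, had folds of 11.5, 40.5 and 11, and the last, from 17718737 to 17718866, had folds of 21.5, 20.3 and 12.3. The other leading regions were the left end of chromosome V (10, 13.1 and 11.3), the region starting at 13657284 on V (21, 17.6 and 10), and on chromosome I the region starting at 933412 (13.8, 12.1 and 11.1) and the widest shared region, from 15060244 to 15071406 (12.7, 15.5 and 9.68). The widest region held 53, 39 and 65 summits, and its input background was 11.5, 11.5 and 11.4 times the genome-wide level in replicates 1, 2 and 3. None of the 20 lay on chromosome II. Fold was higher in replicate 2 than in replicate 3 in 18 of the 20 regions and higher in replicate 1 than in replicate 3 in 15. In the settings run for them, all 20 stayed shared except at 50% reciprocal overlap, where 19 did and the region from 15807396 to 15811206 on X did not.

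**Figure D4:**
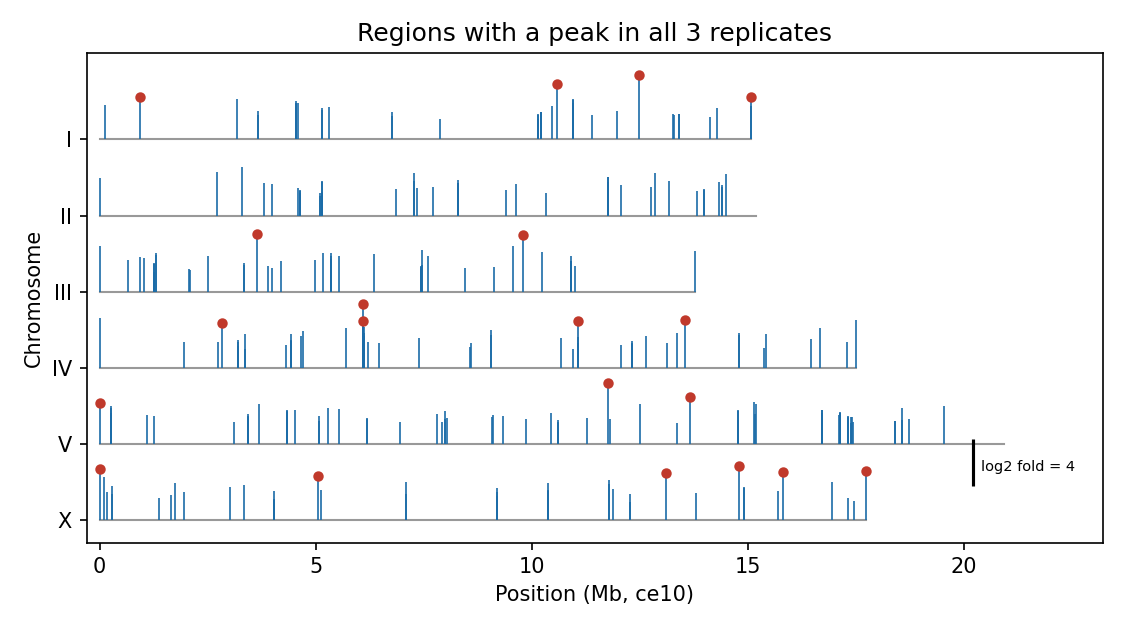
Shared regions (blue lines) along the chromosomes (vertical axis) by ce10 position in Mb (horizontal axis), with line height in log2 of the mean fold over the 3 replicates and a scale bar. Red dots are the 20 leading regions, of which 6 are on X, 5 on IV, 4 on I, 3 on V, 2 on III and none on II.

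Shared regions lay on all 6 nuclear chromosomes. Chromosomes V and IV held 76 and 68, III held 49, and I, II and X held 42 each. By extent this was 3.89 shared regions per Mb on IV, 3.63 on V, 3.55 on III, 2.79 on I, 2.77 on II and 2.37 on X. X is largely silent in germ cells, so its share was compared with the rest. X held 13.2% of the shared regions and 17.7% of the extent (two-sided permutation p = 0.0388, adjusted p = 0.0647 over 5 such tests), which did not pass after adjustment. In the separate lists, peak density on X was 0.836, 0.787 and 0.839 times that on the autosomes, a mean of 0.821 ± 0.0294 (SD, n = 3). The adjusted p of this difference was 0.0647, 0.0202 and 0.098 in replicates 1, 2 and 3 by the same test of random draws. The draws take each peak as independent. Neighbouring peaks of a list were not counted once, so these p-values can be too small. When regions within 10 kb of each other were counted once, 29 of 184 places (15.8%) were on X, and the difference from the extent was not detectable (permutation p = 0.502).

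Shared regions were clustered. Of the 319, 136 (42.6%) lay in 29 runs of at least 3 regions with gaps of at most 10 kb. Random placement of the shared regions put at most 12 in such runs (one-sided permutation p = 0.001, the smallest these can give). Some neighbours in a run nearly touched, such as those ending at 10950411 and starting at 10950455 on I. The placement took each region as independent, so wider signal split into several peaks cannot be told apart from separate sites. After the run of 21 regions on IV, the longest runs had 7 regions each, on III from 7426283 to 7451771 and on I from 10945934 to 10953039. The median folds of these were 4.75, 5.07 and 3.19 on III and 6.5, 5.75 and 7.89 on I in replicates 1, 2 and 3.

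The local input background under the summits differed between regions. Its median over summits was 5.96, 4.24 and 8.0 times the genome-wide level in replicates 1, 2 and 3. In peaks of shared regions the median was 7.21, 5.65 and 7.52 times that level, against 1.26, 1.41 and 1.3 in peaks found in 1 list only. The background was at least 2 times the genome-wide level in all 3 lists for 216 (67.7%) of the shared regions. It was below that in all 3 lists for 58, among them 3 leading regions, those starting at 14790280 and 13104770 on X and at 13657284 on V. Of the 58, 23 lay in the block on IV or in blocks on III (10904177 to 10909882) and II (11756732 to 11762102), the 3 blocks around runs with a median background below 2 times that level. The pileup itself also had a limit. With 1 tag kept per position and strand, it cannot exceed 154, 250 and 110 tags in replicates 1, 2 and 3, and the highest values were 146, 224 and 105. The region placed first, on chromosome I, had these highest values.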

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

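The number of shared regions moved with the definition of a match and with a limit on input background, chosen after the data were seen, which left 60. It was 145 at 50% reciprocal overlap and 601 for presence in at least 2 lists. It lay between 375 and 500 when 1 replicate was left out and a region had to be in both others, the highest without replicate 3. With fold of at least 3 it was 269, with false discovery rate below 0.001 it was 237, with lists of equal length 219, and with summits within 200 bp it was 413 groups of summits. Wherever random placement was run the observed count was above the highest placement, with 200 placements at 50% reciprocal overlap (permutation p = 0.005, the smallest these can give), and none was run for summits within 200 bp. At 50% reciprocal overlap the pairwise shares fell to 24.4% and 26% (replicates 1 and 2), 23.8% and 36.3% (replicates 1 and 3) and 13.4% and 19.3% (replicates 2 and 3). For replicates 2 and 3 this follows in part from construction, since their narrowest peaks (125 and 55 bp) differ too much in width to match. The narrowest peaks of replicate 1 (77 bp) can match those of both other lists, and the cause of the fall in those pairs was not tested. Under that setting r of log2 fold was 0.76 for replicates 1 and 3 and 0.72 for replicates 2 and 3, and with lists of equal length it was 0.64 for replicates 2 and 3. With pileup in place of fold, r was 0.88, 0.89 and 0.82. Pileup is not divided by the local background of the input library that the 3 lists share. These higher values therefore need not mean closer agreement in LAG-1 binding, and their cause was not tested. The share on X stayed between 12.8% and 15.8% in every setting where it was computed. It was not computed under the limit on input background, without chromosome ends and wide regions, or without the 3 runs of low background. The limit on input background kept only peaks with a background below 2 times the genome-wide level. Of the other settings chosen after the data were seen, rotating whole lists kept p at 0.001, removing chromosome ends and regions over 5 kb left 307, and removing the 3 runs of low background left 289. Apart from the named regions, 48 values of the settings fixed before the data were examined stayed within the limits set and 15 moved. The limits were wide for counts, since 237 and 219 shared regions counted as within them, against 319 at an overlap of 1 bp. Not run, since no annotation or sequence of the ce10 build was used here, were the settings for genomic position, gene lists, Notch target genes and the LAG-1 motif. Depth limits the pileups of the lower peaks most, since a pileup of 12 has a 95% interval of 6.20 to 21. Counting error in the sampled input was not computed, and it limits the highest folds as well. At the region starting at 6096542 on IV, folds of 32.5, 69.0 and 28.3 had backgrounds of 4.47, 2.83 and 2.69 times the genome-wide level. That level was 0.671, 0.708 and 0.798 tags in replicates 1, 2 and 3, so these folds rest on few input tags. No paired analysis was possible because no test compared groups of samples.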

Other observations

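The tests of chromosome ends against random placement, of the block on chromosome IV and of the pileup limit, with their bounds, were chosen after the values were seen, as was the change of the reading of the test at chromosome ends given here. The bounds for input background at chromosome ends, in runs and among all shared regions were set before those results.

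Left chromosome ends carried LAG-1 ChIP peaks in nearly every list. Of the 18 combinations of 6 left ends and 3 replicates, 17 had a peak in the first 1000 bp, where random placement gave at most 2 (one-sided permutation p = 0.001, the smallest these can give). The exception was the left end of chromosome I in replicate 3. Folds at the left ends ran from 5.50 to 40.5. At the left end of IV they were 11.2, 39.8 and 6.0 in replicates 1, 2 and 3, and at the left end of III they were 10.7, 26 and 7.60. The input background under them differed as well, at 4.47, 1.0 and 6.27 times the genome-wide level on IV and 4.47, 1.41 and 5.01 times on III, while the pileups on IV were 44, 67 and 35 tags. Along the chromosomes no preference for the centre was detectable. With each extent divided into 3 equal parts, the middle part held 33.5% of the shared regions (exact binomial 95% interval 28.4% to 39.0%, counting error only).

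The 37.0 kb block on chromosome IV was singled out because its run held the most shared regions. Its median input background was 1.49, 1.44 and 1.38 times the genome-wide level in replicates 1, 2 and 3, with upper quartiles of 1.65, 1.94 and 1.64, while the other 28 runs had a median of 8.53 (1.3 to 11.1). Sequence with extra copies in both the ChIP and the input material is argued against by the value of 1.49 for the block as a whole. It is not argued against for 2 of the 21 shared regions, whose background was at least 2 times that level in all 3 lists. They were the strongest, starting at 6096542 (4.47, 2.83 and 2.69), and that starting at 6090193 (2.98, 2.47 and 2.51). Nor is it for regions that reached 2 times that level in at least 1 list but not all 3. The leading region starting at 6094840 (2.64, 1.41 and 1.72) was among these. DNA in extra copies in the ChIP animals and not in the input, such as an introduced construct, could not be told apart from LAG-1 bound all along the block: its fuller flank held 0.667% as many peaks as the block, but beyond the 5 kb that are empty by construction 27 of the 28 other runs stayed within the bound of 10% as well, so the flanks decide nothing, and the same stays open for the blocks on III and II, which hold 5 and 4 shared regions. The labels name no construct and give the same strain for the ChIP samples and the input, while the file headers give the ChIP libraries a name that contains the word Biotag.

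Most shared regions lay where the input itself was high. High input is argued against as the cause of all the sharing, but only for regions of low background. Peaks with a background below 2 times the genome-wide level still gave 60 shared regions, against at most 1 under random placement. Of the 58 shared regions whose highest summits were all below that level, 35 lay outside the blocks on IV, III and II. The test leaves out the 216 shared regions (67.7%) with a background of at least 2 times that level in every list. For these 216 regions, high input stays open as the cause of the sharing. At chromosome ends the background was 4.77 times the genome-wide level, 0.717 times that of the other shared regions (0.589 for the 5 regions at left ends alone), and in runs it was 7.81 times that level, 1.39 times that of regions outside runs. The value at the ends met the bound set beforehand as evidence against extra copies, and that reading was withdrawn only after the value was seen, because the bound assumed a comparator near the genome-wide level and the comparator itself lay at 6.64 times it. Extra copies therefore cannot be told apart from other sources of high input at the ends, nor in runs, where the ratio lay between the bounds.

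In 18 of the 20 leading regions fold was lower in replicate 3 than in replicate 2, with a median ratio of replicate 2 over replicate 3 of 1.56 (quartiles 1.28 and 2.00). Keeping 1 tag per position could compress the strongest summits most in replicate 3, whose median pileup in these regions was 73.6% of the limit, against 48.4% in replicate 1 and 39.8% in replicate 2. That limit is argued against as the whole cause in the 10 leading regions with a pileup below 50% of it in replicate 1, which does not enter the ratio, since their median ratio was 1.70 (quartiles 1.45 and 2.23) with all 10 above 1, at 15.5% to 70% of the limit in replicate 3, against 1.12 over all 319 shared regions. Chosen by replicate 2 instead, 11 of 12 were above 1, with a median of 1.47, and in the 10 leading regions nearer the limit in replicate 1 (median 1.48) the limit cannot be told apart from a lower enrichment in replicate 3, because pileups before removal of duplicates were not used here. The fragment length also differed, at 125 bp in replicate 2 and 55 bp in replicate 3, and whether it changed the ratio was not tested. No biological explanation was tested, since the replicates belong to 1 group.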
